A study of Petunia x hybrida with 12 samples.

How the data were processed

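Polyadenylated RNA was sequenced from pistils of Petunia x hybrida cultivar Mitchell, a white-flowered laboratory petunia. Pistils came from wild-type (WT) plants and from plants carrying an RNA interference construct against the terpene synthase gene PhTPS1 (called tps1 here, after the labels). They were collected at 14:00 on day -1 and day +1 relative to flower opening, and each of the 4 groups held 3 libraries. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so every p-value measures only the spread between these libraries, which may in part be technical.

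The deposited table gives raw read counts, as whole numbers, for 35812 gene IDs in 12 libraries. Per the submitters' processing notes, cutadapt (adapter trimming software), TopHat2 (a spliced aligner) and HTSeq (a read counter) were used by the authors. Their versions, the genome build and the strand setting of the counting are not given in the sources used here. All 12 columns were matched to samples through the column names recorded in the sample descriptions. No column was left unused. The IDs begin with Peaxi162 and a scaffold number, and the file does not pair them with gene names. No annotation or sequence was used here, so IDs are reported as deposited, with no product, coordinate, exon or strand. It follows that the targeted gene PhTPS1 and the genes of the KAI2 pathway were not looked up, and that the RNAi effect on its target was not analysed here. The gene lists fixed before the data were examined (hormones, terpenoids, cell wall, defence, other tissues and similar themes) needed gene names and were not tested. Reads shared between near-identical copies, overlapping genes or antisense genes cannot be recognised from these IDs.

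Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs were kept by filterByExpr (a minimum count of 10, scaled to library size, in at least 3 libraries), which left 21239 IDs holding 99.95 to 99.97% of the counts of each library. Of 2884 IDs carrying a t in place of g, 2 passed this filter, and all of them together held at most 0.000351% of any library. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 12 libraries, so that the 4 groups shared the estimate of spread (common dispersion 0.0607, a biological coefficient of variation of 24.6%). The contrasts were tps1 against WT on each day, day +1 against day -1 in each genotype, and the difference between the genotypes in their change between days. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and the threshold was 0.05. CPM values are the cpm values of edgeR, counts relative to the TMM-scaled library size. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. This is an approximation. Fitted fold changes of IDs with few counts on 1 side depend on the small prior count that edgeR adds, so counts of IDs past a fold size are counts of fitted values.

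Because no names were paired with IDs, the rule written before the data were examined limited the named IDs to the 2 rising and 2 falling IDs with the smallest p in each contrast. IDs named beyond that are said to have been chosen after their values were seen. The pipeline was tested on simulated data, with 200 changed genes planted for each day at the real means, dispersions and library sizes, of which 21099 genes passed the filter. For tps1 against WT at day -1 it recovered 61% of genes changed by 2-fold and 79% of those changed by 4-fold, with 5 false calls among 145. For day +1 the corresponding values were 51% and 74%, with 10 false calls among 135. For the difference in day change they were 30.5% and 70%, with 15 false calls among 216. Each gene was drawn independently, so the simulated libraries held no genes varying together and no library standing apart. The real libraries show both, as described further on, so these rates may not carry over to them.

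Total counts ranged from 19576755 to 30357964 per library. Intervals on counts cover counting error only, since no molecular identifiers are recorded. Between libraries of 1 group, the counts differed far beyond sampling noise (chi-square per degree of freedom from 7.8 to 110), so no library was counted as a duplicate.

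Alternatives were another scaling, 2 other filters on low counts, DESeq2 1.42.0, limma 3.58.1 (voom), fits on only the groups compared, the replicate number as a block, a test against a 1.5-fold change, and leaving out each library in turn. After seeing the data, 5 more were added: voom with library quality weights, removal of a set of IDs that varied together, removal of both day -1 libraries numbered 2, and DESeq2 without that set or without WT day -1 replicate 2.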

Results

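The transcriptome of petunia pistils was measured in 4 groups of 3 libraries: WT and tps1, each at day -1 and day +1. The targeted gene PhTPS1 was not looked up in these libraries, because the file does not pair its IDs with gene names. Between 22935 and 23971 IDs had at least 1 count in a library, and 9068 of the 35812 IDs had none in any library. Total counts per library ran from 21058118 to 30357964 in WT and from 25625763 to 29757361 in tps1 at day -1. At day +1 they ran from 19576755 to 22080654 in WT and from 21356182 to 29614270 in tps1. The first principal component held 85.2% of the variance of log2 CPM and separated the days. WT day -1 replicate 2 stood apart from the other 11 libraries, at -105 on the second component, which held 5.93%. On the first component it lay at -81.94, nearer to day +1 than WT day -1 replicates 1 and 3 (-158.4 and -136.1). The 10 most abundant IDs of a library took 6.42 to 8.14% of its counts at day -1 and 9.24 to 11.4% at day +1. The ID with the highest mean CPM over the 12 libraries took 2.21% ± 0.665 of counts in WT at day -1 and 3.72% ± 0.204 at day +1 (SD, n = 3). In tps1 it took 1.91% ± 0.17 and 3.89% ± 0.179.

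**Figure D1:**
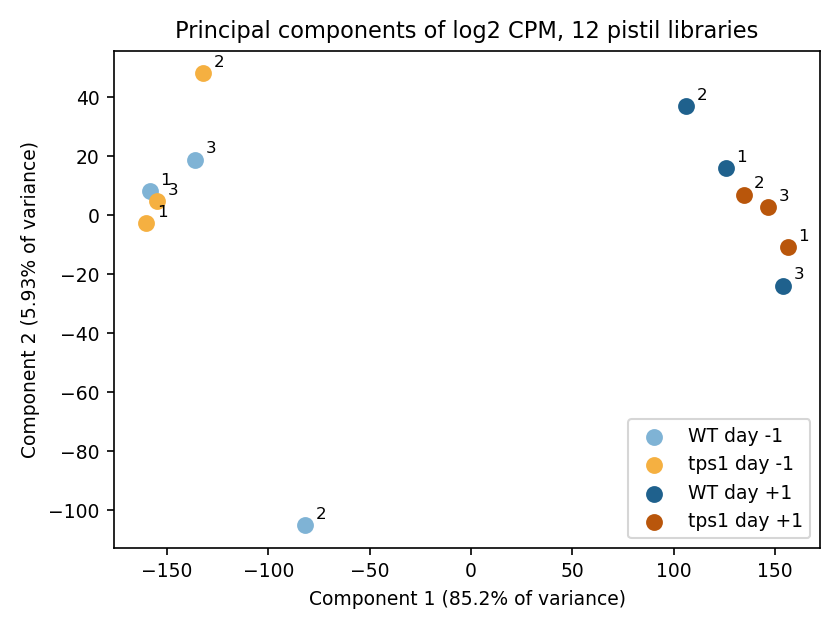
Each point is 1 library, placed by its scores on the first (horizontal, 85.2% of variance) and second (vertical, 5.93%) principal components of log2 CPM, coloured by group and labelled by replicate number. The days separate along the first component, and WT day -1 replicate 2 lies at -105 on the second.

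The day -1 comparison asks which pistil transcripts differ between tps1 and WT before the flower opens. PhTPS1 is a terpene synthase of the petunia flower whose sesquiterpene products reach the pistil as volatiles. The groups hold no plants with a control construct, so an effect of PhTPS1 cannot be told from other differences between the plants. In tps1 pistils, 25 IDs were higher and 14 lower than in WT, 0.184% of the 21239 tested (edgeR quasi-likelihood test, adjusted p under 0.05). By fitted fold change, of the 25 that rose, 18 rose over 2-fold and 6 over 8-fold, and of the 14 that fell, 12 fell over 2-fold and 5 over 8-fold. Peaxi162Scf01082g00028 was 13-fold higher, at 108 ± 2.41 CPM in tps1 against 8.32 ± 2.19 CPM in WT (SD, n = 3; log2 fold change 3.70 ± 0.168 SE, edgeR adjusted p = 1.02e-05). Peaxi162Scf00047g00174 was 5-fold higher, at 127 ± 19 CPM against 25.3 ± 2.76 CPM (log2 fold change 2.32 ± 0.126 SE, edgeR adjusted p = 3.15e-05). Peaxi162Scf00305g00091 was close to the detection floor in tps1, with 10 counts over the 3 libraries against 279 in WT. That is a ratio of WT to tps1 of 31.3, with an exact interval (95%, counting error only) of 16.7 to 65.9 and an edgeR adjusted p of 0.00283. Peaxi162Scf00167g01221 was 1.89-fold lower, at 22.5 ± 1.35 CPM against 42.5 ± 3.76 CPM (log2 fold change -0.92 ± 0.0892 SE, edgeR adjusted p = 0.00327). At all 39 IDs the 3 tps1 values did not overlap the 3 WT values, as chance gives for 10% of IDs and as was found for 7.97% of all tested IDs. The count moved with single libraries, though it stayed within 1.5 times the reported 39 without WT day -1 replicate 3. It fell to 20, 23, 19 and 22 without WT replicate 1, WT replicate 2, tps1 replicate 1 and tps1 replicate 3 of day -1. Fewer libraries also mean less power, which can give such falls. The count was 243 (107 higher, 136 lower) without tps1 replicate 2. It was 364 (156 higher, 208 lower) without both libraries numbered 2 and 399 (113 higher, 286 lower) with DESeq2, so in these 3 settings lower IDs were the more frequent. With DESeq2 it was 186 (85 higher, 101 lower) without the co-varying set described further on and 135 (69 higher, 66 lower) without WT replicate 2. It was 4 when edgeR was fitted to the day -1 libraries alone, where Peaxi162Scf00305g00091 and Peaxi162Scf00167g01221 had adjusted p-values of 0.0873 and 0.164 (the highest over all alternatives were 0.0873 and 0.277).

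The same genotype comparison at day +1 concerns open flowers. More IDs passed the test: 44 were higher and 41 lower in tps1 than in WT, 0.4% of those tested. By fitted fold change, 34 rose and 31 fell over 2-fold, with 6 in each direction over 8-fold. The IDs with the smallest p among those that rose were again Peaxi162Scf01082g00028 and Peaxi162Scf00047g00174. Peaxi162Scf01082g00028 was 22.9-fold higher, at 113 ± 3.85 CPM in tps1 against 4.91 ± 0.481 CPM in WT (SD, n = 3; log2 fold change 4.52 ± 0.177 SE, edgeR adjusted p = 2.18e-06). Peaxi162Scf00047g00174 was 7.09-fold higher, at 118 ± 6.86 against 16.6 ± 1.25 CPM (log2 fold change 2.83 ± 0.13 SE, edgeR adjusted p = 5.57e-06). Peaxi162Scf00167g01221 was 2.16-fold lower, at 8.97 ± 0.32 against 19.4 ± 1.56 CPM (log2 fold change -1.11 ± 0.0919 SE, edgeR adjusted p = 0.000935). Peaxi162Scf00052g01815 was 2.58-fold lower, at 7.02 ± 1.09 against 18.2 ± 1.13 CPM (log2 fold change -1.37 ± 0.129 SE, edgeR adjusted p = 0.0014), and at day -1 it stood at 118 ± 15.9 CPM in tps1 and 145 ± 8.69 CPM in WT (edgeR adjusted p = 0.588). The difference between its genotype effects on the 2 days was not past the threshold (-1.07 on the log2 scale, edgeR adjusted p = 0.186). At all 85 IDs the tps1 and WT values did not overlap, and this held for 23.9% of all tested IDs, against 10% by chance. Another split of the day +1 libraries, which mixed the genotypes, gave 18.7%, so a share above 10% can arise apart from genotype. With 1 day +1 library left out, the count was 40, 46 and 50 without WT replicates 1, 2 and 3, and 26, 54 and 34 without tps1 replicates 1, 2 and 3. It was 195 (118 higher, 77 lower) with the day +1 libraries fitted alone, 316 (121 higher, 195 lower) with DESeq2 and 169 without both day -1 libraries numbered 2. Which day had more calls depended on the setting. Day -1 had more with DESeq2 (399) and without tps1 day -1 replicate 2 (243, against 126 at day +1). It had fewer with each day fitted alone (4).

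**Figure D2:**
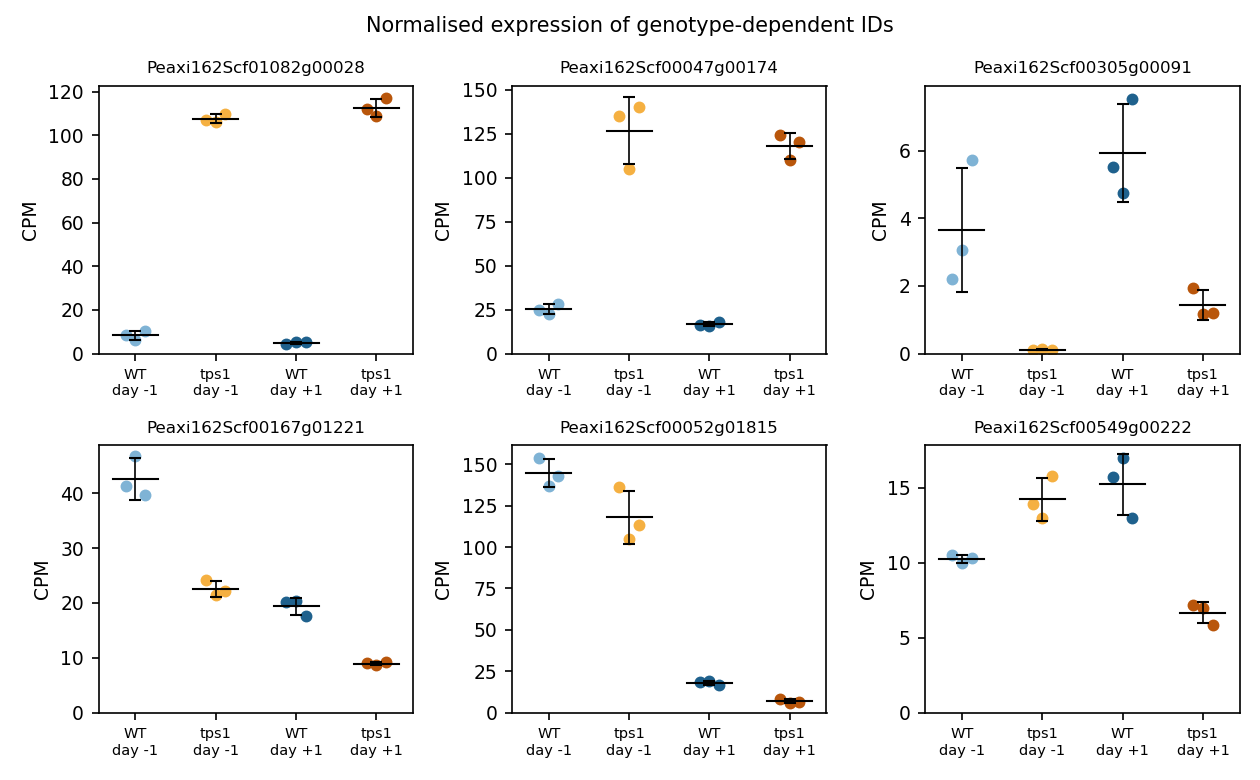
CPM (vertical axis, linear from 0) of the 6 IDs named in the genotype comparisons, with 3 points per group, a line at the mean and bars of 1 SD. Peaxi162Scf01082g00028 was at 108 CPM in tps1 against 8.32 CPM in WT at day -1, and Peaxi162Scf00549g00222 was at 6.67 CPM in tps1 against 15.2 CPM in WT at day +1.

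The genotype comparisons of the 2 days use the means of different libraries, but their calls share 1 estimate of spread per ID. Of the 39 IDs called at day -1 and the 85 called at day +1, 22 were called on both days. Of these, 17 were higher and 5 lower in tps1 on both days, and 0 changed in opposite directions. Independent lists of these sizes would share 0.0518 higher and 0.027 lower IDs, a value that leaves the shared spread out. With edgeR fitted to each day alone, which shares no spread, 4 IDs were called at day -1 among the 18642 tested in both fits, and 4 of these 4 were also among the 182 called at day +1, all of them higher in tps1 on both days (0.0236 by independent lists). Across the 22 IDs, which are not independent replicates and were selected for passing both tests, the log2 fold changes of the days correlated with r = 0.93. Their median ratio of day +1 to day -1 was 1.1. Among IDs called at day -1, 37 of 39 had the same sign at day +1, and among IDs called at day +1, 66 of 85 had the same sign at day -1. Over all tested IDs the sign was shared by 55.2%, and the correlation across genes was 0.0081.

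**Figure D3:**
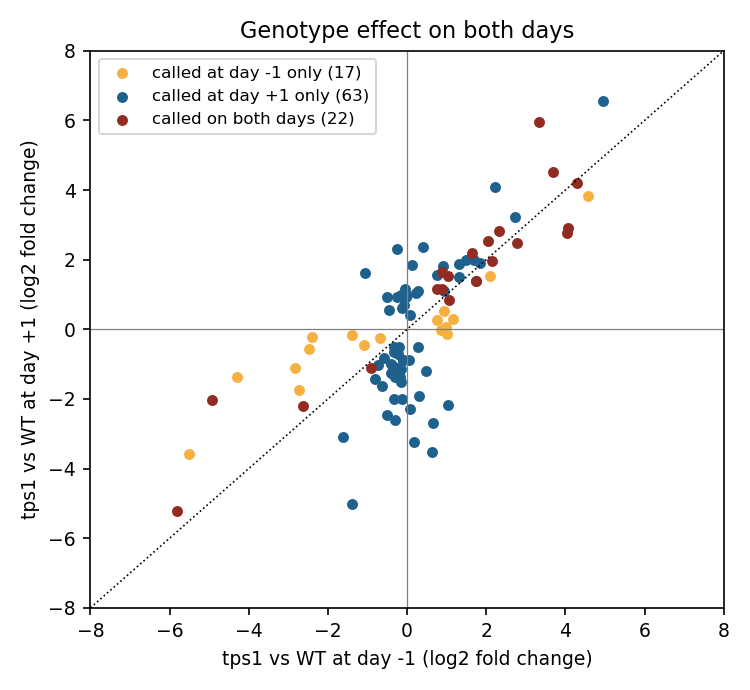
Log2 fold change of tps1 against WT at day -1 (horizontal) and day +1 (vertical) for the 102 IDs called on either day, coloured by the day of the call, with a dotted line of equality. The 22 IDs called on both days all lie in the quadrants of shared sign.

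Whether the genotype effect differed between the days was tested directly. It did for 1 ID, Peaxi162Scf00549g00222, which was at 10.3 ± 0.27 CPM in WT and 14.2 ± 1.4 CPM in tps1 at day -1, and at 15.2 ± 2.05 CPM in WT and 6.67 ± 0.7 CPM in tps1 at day +1 (SD, n = 3). It rose between the days in WT (log2 fold change 0.57, edgeR adjusted p = 0.00227) and fell in tps1 (-1.09, edgeR adjusted p = 3.07e-05). The difference of these changes was -1.66 ± 0.176 SE on the log2 scale (edgeR adjusted p = 0.0439). The edgeR call was kept without tps1 day -1 replicate 2 or WT day +1 replicate 3 (adjusted p = 0.0217 and 0.0262) and lost without any 1 of the other 10 libraries, with adjusted p up to 0.188 (up to 0.373 over all alternatives). The count was 4 without tps1 day -1 replicate 2, 0 without any 1 of those 10 libraries, 0 with limma-voom and 92 with DESeq2. The edgeR model gave an unadjusted p under 0.05 for 1300 IDs.

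The comparison of days asks how the pistil transcriptome changes as the flower opens. In WT, 6641 IDs were higher and 7120 lower at day +1 than at day -1, 64.8% of those tested (edgeR quasi-likelihood test, adjusted p under 0.05), with 3250 higher and 3905 lower by over 2-fold (fitted). Peaxi162Scf01434g00015 rose 64-fold, from 1.84 ± 0.0892 to 118 ± 9.45 CPM (SD, n = 3; SE 0.138 on the log2 scale, edgeR adjusted p = 3.21e-09). Peaxi162Scf00001g10525 rose 53.6-fold, from 0.495 ± 0.0339 to 26.8 ± 2.53 CPM (log2 fold change 5.74 ± 0.129 SE, edgeR adjusted p = 3.21e-09). Peaxi162Scf00021g00132 was 81.4-fold lower at day +1, at 1.94 ± 0.168 against 158 ± 12.8 CPM (log2 fold change -6.35 ± 0.153 SE, edgeR adjusted p = 3.61e-09). Peaxi162Scf00691g00316 was 29.9-fold lower, at 8.2 ± 1.06 against 245 ± 5.63 CPM (log2 fold change -4.90 ± 0.113 SE, edgeR adjusted p = 3.21e-09). Fitted changes over 8-fold numbered 1193 upwards and 908 downwards, and outside the set of 585 co-varying IDs described further on, 788 and 908. IDs at 1 CPM or more in each WT day +1 library and under 0.1 CPM in each WT day -1 library numbered 113, and the reverse pattern was found for 57.

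In tps1, 6761 IDs were higher and 6999 lower at day +1, with 3470 and 3818 by over 2-fold. The leading IDs were those of WT. Peaxi162Scf01434g00015 rose 81.9-fold to 115 ± 9.38 CPM (log2 fold change 6.36 ± 0.141 SE, edgeR adjusted p = 3.29e-09), and Peaxi162Scf00001g10525 rose 46.7-fold to 24.7 ± 1.83 CPM (SD, n = 3; log2 fold change 5.55 ± 0.126 SE). Peaxi162Scf00691g00316 was 28.8-fold lower at day +1, at 8.33 ± 0.0935 CPM, and Peaxi162Scf00021g00132 was 59.5-fold lower, at 2.4 ± 0.451 CPM (edgeR adjusted p = 3.29e-09 and 4.66e-09). The changes of the 2 genotypes rest on the means of different libraries and on 1 shared estimate of spread per ID. They shared 12232 called IDs, of which 5862 rose in both, 6366 fell in both and 4 moved in opposite directions. Independent lists would share 2110 rising and 2350 falling IDs. With edgeR fitted to each genotype alone, 5131 IDs rose and 5940 fell in both, against 1870 and 2180 by independent lists. Over all tested IDs the log2 fold changes of WT and tps1 correlated across genes with r = 0.89, and 91.5% had the same sign. IDs at 1 CPM or more in each day +1 library and under 0.1 CPM in each day -1 library numbered 392 in tps1, of which 231 belonged to the set of IDs described next. In WT that set gave 19 of the 113. The median member stood at 4.3 and 0.252 CPM in WT day -1 replicates 2 and 3, above the limit of 0.1 CPM. These numbers therefore do not compare the genotypes.

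**Figure D4:**
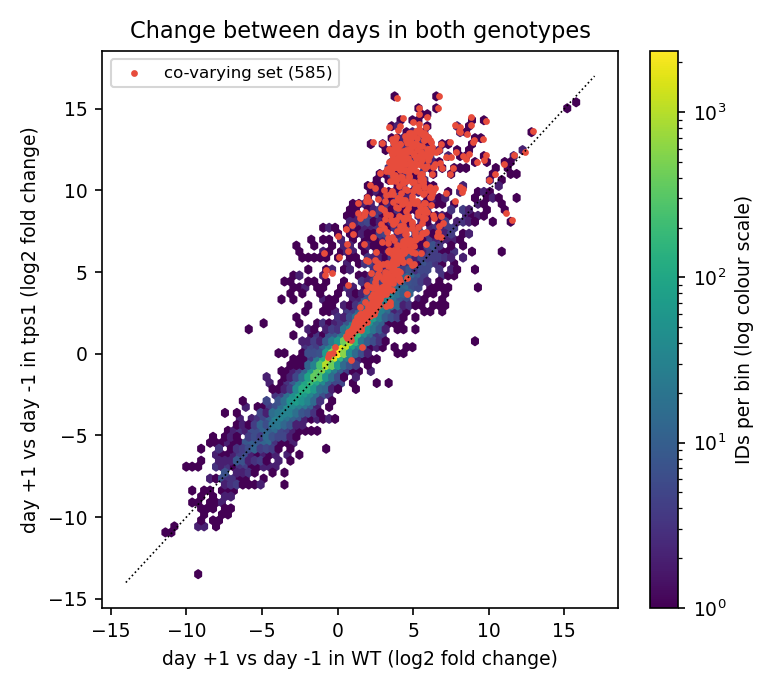
Log2 fold change of day +1 against day -1 in WT (horizontal) and tps1 (vertical) for the 21239 tested IDs, binned with a log colour scale, with a dotted line of equality and the 585 IDs of the co-varying set in red. Most IDs lie along the line (r = 0.89), and 481 members of the set in WT and 569 in tps1 were called higher at day +1. The gap between these numbers rests largely on WT day -1 replicate 2.

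A set of 585 IDs differed by at least 4-fold between WT day +1 replicates 3 and 2, at a mean of at least 5 CPM over the WT day +1 libraries, all of them higher in replicate 3. In the opposite direction 0 IDs met the same criteria. The set was defined after the data were seen. It took 2.99, 1.42 and 11% of the counts in WT day +1 replicates 1, 2 and 3, and 8.94, 4.85 and 6.01% in the tps1 day +1 replicates. At day -1 it took 0.187 to 0.247% in 5 libraries and 1.07% in WT replicate 2. The median member stood at 4.3 CPM in that library, against 0.0442 and 0.252 CPM in WT replicates 1 and 3. Within day +1 the set took 6.6% ± 2.11 of counts in tps1 and 5.14% ± 5.14 in WT (SD, n = 3). An exact two-sided permutation test of these shares gave p = 0.7 (n = 3 each; the smallest p this design allows is 0.1), which decides nothing, because the set was chosen for its spread between WT libraries. In the day comparisons, 481 members were called higher at day +1 in WT and 569 in tps1. DESeq2 called 484 members between days in WT and 577 in tps1. Without WT day -1 replicate 2 it called 566 and 576, so this gap between genotypes rests largely on that library. The edgeR genotype calls of either day included 0 members of the set, while 149 of the 399 IDs called by DESeq2 at day -1 were members. The 0 says nothing about a genotype effect on the set. Choosing members for their spread between WT libraries works against an edgeR call, and the set is only 585 of the 21239 tested IDs.

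**Figure D5:**
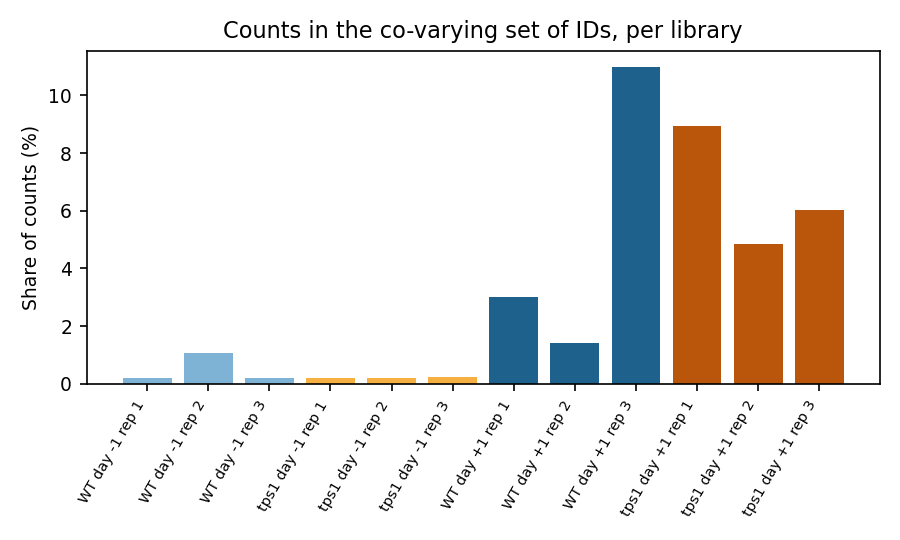
Share of each library's counts (vertical axis, percent, from 0) taken by the 585 IDs of the co-varying set, with 1 bar per library coloured by group. The share runs from 1.42 to 11% within WT day +1, and at day -1 it exceeds 0.247% only in WT replicate 2, at 1.07%.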

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

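The tests of the co-varying set (in WT day -1 replicate 2 and tps1 day -1 replicate 2 too), of exchanged labels and of chance placement on scaffolds were chosen after the results they bear on had been seen. The genotype effect on Peaxi162Scf00549g00222 differed between the days by -1.66 on the log2 scale, the 1 case in which an interaction passed its threshold. Among 60 assignments of genotype within each day, the real one included, 3 gave at least 1 such ID, and the highest of the others gave 5. This share of 0.05 met the bound, at least 0.05, that was set beforehand for a count that chance gives. The drawn assignments with such IDs (5 and 1) kept the WT and tps1 libraries of day +1 apart. Their calls can therefore carry the genotype effect of that day. Other drawn assignments that also kept these libraries apart gave 0. Every drawn assignment that mixed the genotypes at day +1 gave 0. These draws neither exclude chance for this count nor show that chance gives it.

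The 585 IDs that varied together are the first pattern. Members were chosen on WT day +1 libraries, and 98.6% of them kept 1 ratio, within 0.5 log2 of their median, between tps1 day +1 replicates 1 and 2, while 1.99% of 14248 other IDs lay in that same window. For the day +1 libraries this is consistent with RNA from 1 other tissue or cell type entering in differing amounts, though it is not named here and a programme switched as a block in the pistil was not tested. Later sampling of WT day -1 replicate 2 is argued against, since 376 IDs outside the set had gone a median fraction of -0.000927 of the way from WT day -1 replicates 1 and 3 to the WT day +1 mean there, against 0.103 for 581 members of the set whose WT day +1 mean was over 1 CPM higher (the 376 are IDs called in tps1 with a rise over 8-fold between days, which also rose over 8-fold from those WT replicates to a WT day +1 mean of at least 5 CPM). In the other direction, WT day -1 replicate 2 lay towards day +1 on the first principal component (-81.94, against -158.4 and -136.1 for WT replicates 1 and 3). What moved it there was not tested. Genotype stays open: the set's share in 3 of the 3 tps1 day +1 libraries fell within the WT range, but choosing the set for its spread in WT made that range wide, so this decides nothing.

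The second pattern is tps1 day -1 replicate 2, without which 243 rather than 39 IDs differed between genotypes at day -1. RNA of the co-varying set is argued against, since that library held 0.826 times the set's share of the other 2 tps1 libraries. Exchanged labels of the libraries numbered 2 are argued against too, because the 85 IDs called at day +1 placed 6 of the 6 day -1 libraries on the side of their own label. A later stage of these pistils stays open: over IDs with a day change over 4-fold in WT, the library's deviation had a slope of 0.0715 on that change, between the bounds set for and against it before that slope was computed. Rising IDs were shifted by a median of 0.248 and falling IDs by -0.175 on the log2 scale. The deviation of tps1 day -1 replicate 2 from its group mean resembled that of WT day -1 replicate 3 (correlation across IDs 0.53). With WT day -1 replicates 1 and 2 the correlations were -0.23 and -0.18. Deviations from a group mean cancel out within the group, so the negative values are not separate evidence. A WT library thus deviated in a similar way, but this does not show that it moved the count of genotype calls. The cause of this resemblance was not tested.

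The third pattern is the placement of the genotype calls. Of 102 IDs called on either day, 31 shared a scaffold number with another called ID, against a median of 19 in random sets. A share of 0.0193 of the 10000 random sets held as many, which argues against chance placement. A chromosome segment that differs between the RNAi line and WT may contribute: 28 of the 31 had the same sign on both days, as did 53 of the 71 other calls, so sign alone says little, and uncalled IDs within 3 IDs of a call on the same scaffold had a median absolute effect of 0.15 against 0.135 in expression-matched draws, reached by a share of 0.0275 of draws. The called IDs of a scaffold moved in 1 direction on some scaffolds and in opposite directions on others. Examples, chosen after their values were seen, are Peaxi162Scf03648 and Peaxi162Scf00305. Their log2 fold changes at day +1 were 1.95 and 2.77 on the first, and -2.04 and 1.85 on the second. The rising IDs named on both days were among the 31, also looked up after the values were seen. Peaxi162Scf01082g00028 (4.52 at day +1) shared its scaffold with Peaxi162Scf01082g00025 (4.21), Peaxi162Scf01082g00113 (2) and Peaxi162Scf01082g00314 (-1.37). Peaxi162Scf00047g00174 (2.83) shared its scaffold with Peaxi162Scf00047g00334 (-1.08) and Peaxi162Scf00047g02318 (-1.37). Reads shared between copies would not give opposite directions. Where the direction is shared, neighbouring copies that share reads, or neighbours regulated together, stay open because no sequences were used.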

How the results depend on the processing

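The direction of every named ID was kept under all alternatives run, and of 424 values for named IDs 408 stayed past the threshold; 13 of the 16 losses were Peaxi162Scf00549g00222, and the others were Peaxi162Scf00167g01221 and Peaxi162Scf00305g00091 at day -1. The counts for the genotype comparisons were not stable. Those at day -1 and day +1 were 15 and 36 against a 1.5-fold change, 23 and 52 with the replicate number as a block, 4 and 195 with only the groups compared, 399 and 316 with DESeq2, 81 and 941 with library weights in limma-voom, and 364 and 169 without both day -1 libraries numbered 2. With 1 library left out they ranged from 19 to 243 and from 26 to 126. DESeq2 gave 186 and 325 without the co-varying set and 135 and 338 without WT day -1 replicate 2. The set accounts for part of the DESeq2 rise to 399 at day -1, since 149 of those IDs were members, and the rest has no tested cause. Leaving out WT day -1 replicate 2 left 0 members among the calls. It also removed a sample, and DESeq2 was run without no other single library. What that library adds to the rise beyond the set therefore cannot be told. The weights and every removal of the set, of that library under DESeq2 or of both libraries were chosen after seeing the data. For the other shifts the cause was not tested, apart from the stricter null of the 1.5-fold test. The difference in day change gave 2 IDs with DESeq2 size factors, 2 without the co-varying set, 92 with DESeq2 (79 without the set, 84 without WT day -1 replicate 2), 22 with library weights, 10 without both libraries, and 0 against a 1.5-fold change, with the replicate block and with limma-voom (546, 898 and 864 at an unadjusted p under 0.05). With 1 library left out it ranged from 0 to 4. The day comparisons gave 7575 IDs in WT and 7832 in tps1 against a 1.5-fold change, and 24 of 25 alternatives stayed within 1.5 times the reported count for each. With 1 library left out they ranged from 12625 to 14515 and from 12299 to 14325. No label says that the replicate numbers of the block pair the libraries: of 18 pairs with the same number in different groups, 3 deviated together with a correlation over 0.1 (range -0.58 to 0.36), and 2 of 12 libraries correlated best with their own number. The gene list tests with other correlations, a block and fry were not run, because no ID has a name. For both genotype comparisons and both day comparisons the libraries allow only 10 splits, too few for a share under 0.05. At day -1, 2 of the 10 gave at least the real 39 IDs, and the highest other, which joined tps1 replicate 2 with WT replicates 1 and 3, gave 229, which points to a structure among these libraries apart from genotype. At day +1 the real split gave 85 and the highest other 0, with 1 split as large. The day comparisons gave 13761 and 13760, with 0 in every other split. Depth limits what is said of IDs near the floor such as Peaxi162Scf00305g00091.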

Other observations

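The tests in this part were chosen after the values were seen. WT day -1 replicate 2 carried 181 IDs at 5 CPM or more that averaged under 0.5 CPM in WT day -1 replicates 1 and 3. Of these, 135 belonged to the set, and 25 stood over 4-fold above their level in each day +1 library. Set members in that library also kept no single ratio to WT day +1 replicate 3: the interquartile range of the log2 ratio was 1.89, against 0.169 for tps1 day +1 replicate 1. The 562 IDs that were called lower by over 8-fold between days in tps1 and averaged at least 5 CPM in WT day -1 replicates 1 and 3 had a median shift of -0.0117 on the log2 scale in WT day -1 replicate 2, relative to that average.

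A hypothesis is that small genotype effects may be spread over many IDs at day +1. The tps1 and WT libraries did not overlap for 23.9% of tested IDs, and the highest of the other 9 splits gave 18.7%. Without the co-varying set the values were 24.6% and 16.4%. At day -1 the real split gave 7.97%, and the highest other split gave 18.6%. With 10 splits no share under 0.05 can be reached. IDs that vary together move as a block in such counts, so the hypothesis stays open.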
